A study of Mus musculus with 4 samples.

How the data were processed

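RNA from purified microglia was extracted with Trizol and made into libraries with a SMARTER mRNA-seq kit, per the labels' protocols. FastQC 0.11.2, HISAT2, featureCounts and the genome build GRCm38 are named in the submitters' processing notes, without their roles or settings. The deposited table gives an FPKM and a count column under each of 4 names, per the file headers, which do not say how many libraries these are. The count columns hold fractional values for some genes, and the step that made them fractional is not given in the sources used here.

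Groups were taken from the sample titles. A column was to be used only where its name matched the labels of a sample or group. Each column name, with and without its last part, was searched for in all sample labels and in the series text, and none was found. Column order, accession order and the expression of Gpr34 were not used to assign genotypes. All 8 value columns were left out for this reason, and no test between genotypes was run. The columns were looked at to find their units. In that inspection some Gpr34 counts were seen, and a chi-square comparison of rounded counts found far smaller differences between columns that share the first part of their name than between columns that do not. The differences within such pairs were still larger than counting error alone, the only error this comparison covers, and the cause was not tested. The counts were in part fractional and were rounded for this comparison. No columns known to be separate libraries of the same group were available for reference. The comparison therefore cannot decide whether each pair is 1 library sequenced in separate runs. If each pair were 1 library, the table would hold no biological replicates. This comparison was a single look, and its values are not given. Neither look was used further. The planned differential expression and gene list tests, and every alternative planned for them, were not run.

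The gene identifiers and symbols of the table were compared with GENCODE M21 (GRCm38) by identifier without version. Members of the gene lists were looked up by symbol. As alternatives, rows were matched to the annotation by symbol, and list members by symbol or RefSeq synonym. Tables were read with pandas 2.3.3.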

Results

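RNA sequencing was used to profile purified microglia, the resident macrophages of the brain, from mice aged 9 months. The design has 4 samples in 2 groups: 2 samples labelled 5xFAD and 2 labelled Gpr34 deficient. 5xFAD is a transgenic mouse line used as a model of Alzheimer's disease, and Gpr34 encodes a G protein-coupled receptor. The comparison the design implies is Gpr34-deficient against 5xFAD microglia. The series text gives its purpose as the effect of the receptor on microglia in 5xFAD mice, but the labels of the Gpr34-deficient samples do not say whether those mice also carried the 5xFAD transgenes. The labels do not say whether the samples of a group came from separate animals.

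No expression level, fold change or test is given for this comparison. The deposited expression table has 8 columns of values, an FPKM and a count, fractional for some genes, under each of 4 names. The names share a first part in pairs, and the same last parts occur under each first part. Whether each pair is a pair of separate libraries or repeat sequencing runs of a single library is not stated in the sources used here. The 4 names therefore cannot be taken as 4 replicate libraries. The names of these columns appear in no sample's labels and not in the series text, so 0 columns could be placed in a genotype. Gpr34 itself is therefore not reported by group, and depth per sample is not reported.

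Gpr34 (ENSMUSG00000040229) has a row in the table. In the GENCODE M21 annotation of GRCm38 it is a protein-coding gene on the plus strand of chromosome X, from 13632089 to 13640858. Transcript ENSMUST00000041708 has 4 exons, and its coding sequence lies wholly in exon 4, from 13639234 to 13640358. The gene lies within the span of Cask (ENSMUSG00000031012), which runs on the minus strand from 13517080 to 13851367. Gpr82 (ENSMUSG00000047678) also lies inside Cask, on the plus strand from 13661363 to 13667433. The strand setting of the read counting is not given in the sources used here. Whether exons of Cask overlap exons of these genes was not examined. It is therefore not known whether their reads are separable in such a table. The labels do not state how Gpr34 was made deficient.

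The table as used here has 22337 gene rows, of which 22232 (99.53%) carry an identifier found in GENCODE M21. Protein-coding genes make up 21759 of the matched rows. Of the 818 different symbols in the 39 gene lists fixed before the data were examined, 808 have a row under the same symbol. All 35 genes of the disease-associated microglia list, which includes Apoe, Trem2 and Clec7a, have a row. Of the 30 symbols on the homeostatic microglia list, which includes P2ry12, Tmem119 and Cx3cr1, 28 have one, and all 30 do when RefSeq synonyms are allowed. That list holds Gpr56 and Adgrg1, names of the same gene, so its symbols are not all different genes. All 28 inflammatory cytokine and chemokine genes and all 16 oligodendrocyte and myelin markers have a row. Of the 6 sex-linked genes, 4 have a row, and Xist and Tsix have no row under their symbol or a RefSeq synonym. These counts describe which genes the table lists and say nothing about their expression.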

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

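No paired analysis was possible because no column of the table could be matched to a sample, so the replicate numbers in the titles belong to no column. For the same reason none of the alternatives planned before the data were examined was run. The alternatives given here were chosen after seeing the data. Matching rows to GENCODE M21 by symbol found 21672 rows, against 22232 by identifier. Allowing RefSeq synonyms raised the list symbols with a row from 808 to 811. The symbols gained were Gpr56, Mboat5 and Tmem173. Gpr56 and Mboat5 are other names of Adgrg1 and Lpcat3, which the lists also hold, so only Tmem173 added a gene.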
